A study of Homo sapiens with 4 samples.

How the data were processed

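The data are 4 whole-transcript microarrays of Caco2 cells, 2 treated with vehicle and 2 with cudraflavone C. Per the labels' protocols, total RNA was isolated with a column kit, reverse transcribed, converted to biotin-labelled single-stranded DNA and hybridised to the Affymetrix Human Transcriptome Array. The deposited values are RMA summaries on the log2 scale, 1 column per array, and per the submitters' processing notes GCOS, the Affymetrix Expression Console and RMA were used. Versions, the genome build and the annotation release are not given in the sources used here. RMA corrects background, makes the arrays' intensity distributions equal by quantile normalization and summarises probes, so a shift shared by all transcripts cannot be seen in these values. The deposited log2 scale was checked against the range of the values.

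The table holds 70523 features, of which 67528 transcript clusters were tested and 2995 control and other features were left out, among them 1465 probe selection regions and junctions and 155 spike-in features. No filter on dim clusters was applied. The 23 background features had a median level of 1.75, and 36.3% of clusters had a mean at or below it, so many clusters carry little signal over background. Of the clusters, 23781 name 1 gene in the platform annotation supplied, 1543 name several and 42204 name none here. Symbols were updated through the gene IDs and synonyms of a RefSeq gene table of assembly GRCh38.p14, which changed 306 of them, and 23777 of the 23781 clusters then had a symbol in that table. As the files' build is not stated, no coordinates are given. A gene's value is that of its cluster with the highest mean over all 4 arrays, which gave 22411 genes. Of the genes named, CYP1B1 has a further, dimmer cluster, which differed by 0.034 where the cluster used differed by 0.24. In 2382 clusters all 4 values equal those of another cluster, as near-identical copies share probes.

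Groups were taken from the labels. Treated and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with no trend, 2-sided), without a block, and p-values were adjusted by the Benjamini-Hochberg method over all clusters with a threshold of 0.05. Control and treated means are given with the SD over 2 arrays, and differences with limma's moderated standard error. Gene groups are 44 lists written before the data were examined, as were the test, the alternatives and the rule for named genes. Lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, which left 43 lists, adjusted together. Beside it stand camera with an estimated correlation, fry, and counts of members adjusted over the list alone. With 2 arrays per group an estimated correlation is itself imprecise. The lists hold 918 distinct genes, of which 770 were measured by a cluster naming 1 gene here. A group was called separated where both treated arrays lay on the same side of both control arrays.

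Named genes were the 12 largest rises and 12 largest falls past the threshold with separated groups. As none passed, they were filled by the smallest unadjusted p among genes with an absolute log2 difference of at least 0.5, and separation was required of these too. From each list past the camera threshold up to 5 members with the largest moderated t in its direction were eligible, and from any other list described up to 4. Uncharacterised symbols and small RNA families were not named by this rule.

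The scripts were tested on simulated data with the means and spread of these arrays. Alternatives were further normalizations, filters on dim clusters, other variance models, array weights, a replicate block, leaving out each array, other thresholds and tests, and the mean of a gene's clusters. Random lists matched on mean expression, 10000 for each list in 50 bins, were added after seeing the data. A list of actin cytoskeleton genes was written after the leading genes had been seen, without those genes, and before it was tested. The comparison of snoRNA with snRNA genes was run first on all snoRNA genes and then limited to those with a mean of at least 3, because most lay near background, and both outcomes are given.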

Results

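Gene expression was measured in Caco2 cells, a human colorectal cancer cell line, after 48 h with 10 uM cudraflavone C, a prenylated flavonoid of plants of the mulberry family, or with the 0.1% DMSO vehicle alone. The DMSO content of the treated samples is not given in the sources used here. Each group had 2 arrays, and each array gave RMA expression values on the log2 scale for 67528 transcript clusters, which are the array's gene-level units. The comparison asks which transcripts differ between treated and vehicle cells. Median values per array ran from 1.95 to 1.97, and the 4 arrays correlated with each other at Pearson r of 0.9816 to 0.9933 across clusters, which are not independent replicates. The control arrays lay further apart than the treated ones: among clusters with a mean of at least 4, the median absolute difference between replicates was 0.183 in Control and 0.0763 with cudraflavone C. Control replicate 2 correlated more closely with the treated arrays (r of 0.9896 and 0.9888) than with Control replicate 1 (0.9835). By this measure the arrays did not group by treatment. The number of arrays limits the precision, and nothing states that the duplicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

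Of genes outside the small RNA families whose means differed by at least 0.5 and whose groups were separated, 55 were higher with cudraflavone C and 4 lower, and several of the 12 leading higher genes encode transcription factors or actin-linked proteins. Over all clusters the directions were closer to balance, with 73 higher and 56 lower at an unadjusted p under 0.001. ZSWIM6, a zinc finger gene, had a mean of 7.44 ± 0.016 (SD, n = 2) with the compound and 6.21 ± 0.15 (SD, n = 2) in Control, a difference of 1.23 ± 0.090 (SE) or 2.35-fold. The transcription factor genes KLF7 and EGR1 were higher by 1.03 ± 0.080 and 1.06 ± 0.11 (SE), and BHLHE41, HES1 and BCL6, which encode transcriptional repressors, by 0.67, 0.75 and 0.66. VCL, which encodes vinculin of focal adhesions, was higher by 1.06 ± 0.097 (SE), and ACTN1, which encodes the actin cross-linker alpha-actinin 1, by 0.72 ± 0.061 (SE). TANC2, a synaptic scaffold gene, differed by 0.93, TUBB2A, a beta-tubulin gene, by 0.60, JUP, which encodes plakoglobin of cell junctions, by 0.56, and SRPRA, which encodes a subunit of the signal recognition particle receptor, by 0.51. In each of these 12 genes both treated arrays lay above both control arrays. None passed the adjusted threshold (limma with Benjamini-Hochberg adjustment, adjusted p from 0.399 to 0.477).

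The 4 genes that met the naming rule in the other direction were led by HSPA5. HSPA5, which encodes the main chaperone of the endoplasmic reticulum, had a mean of 4.02 ± 0.19 (SD, n = 2) with cudraflavone C and 4.81 ± 0.072 (SD, n = 2) in Control, a difference of -0.79 ± 0.11 (SE). GPX2, which encodes an intestinal glutathione peroxidase, differed by -0.74 ± 0.16 (SE), with control arrays that were themselves spread by an SD of 0.32. FST, which encodes the activin-binding protein follistatin, differed by -0.58 ± 0.085 (SE), and the histone pseudogene H2BC20P by -0.55 ± 0.087 (SE). The adjusted p of these 4 genes lay between 0.491 and 0.499 in limma, so none passed.

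**Figure D1:**
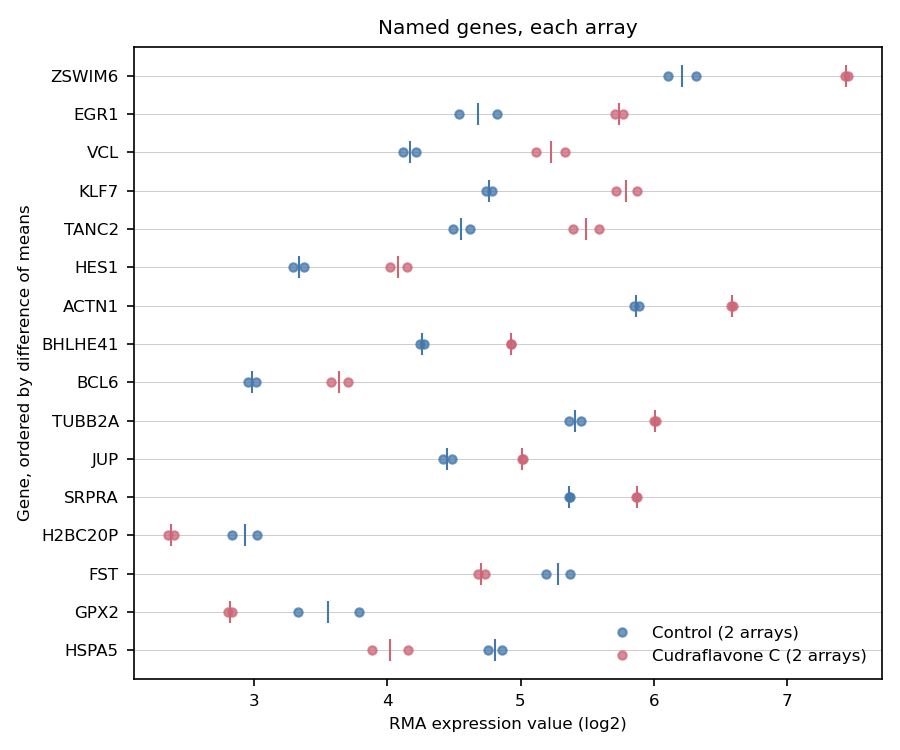
RMA expression values (log2, horizontal axis) of the 16 named genes on each of the 4 arrays, with points for arrays and vertical ticks for group means, ordered by the difference of means. Both cudraflavone C arrays lie above both Control arrays for the 12 genes from ZSWIM6 to SRPRA and below them for H2BC20P, FST, GPX2 and HSPA5, though none passed the adjusted threshold.

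Across all 67528 clusters, limma with Benjamini-Hochberg adjustment called 0 higher and 0 lower at an adjusted p under 0.05, with or without a 2-fold limit, and the smallest adjusted p was 0.343. At an unadjusted p under 0.05, 2641 clusters were higher and 2746 lower, against 3376 expected by chance in both directions together. These unadjusted counts moved with single arrays: they were 2468 higher and 4231 lower without Control replicate 1, 7393 and 5953 without Control replicate 2, 1170 and 807 without Cudraflavone C replicate 1, and 1057 and 757 without Cudraflavone C replicate 2. Means differed by at least 2-fold in 34 clusters that were higher and 16 that were lower. Of these, 4 name a single gene here, all of them higher (ZSWIM6, EGR1, VCL and KLF7), and the others, 30 higher and 16 lower, carry no gene name in the annotation used. On simulated data of this size, 44 of 67 clusters changed by 2-fold were called (65.7%) and 0 of 67 changed by 1.5-fold. The same simulation held 66 clusters changed by 4-fold, of which 65 were called. Such changes ease the adjusted threshold for the other clusters, so 65.7% may overstate what could be called here. The simulated noise was also independent between clusters and equally wide in both groups. On the arrays, replicates differed by a median of 0.183 in Control and 0.0763 with cudraflavone C among clusters with a mean of at least 4. The share that could be called here may therefore differ.

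Genes of endoplasmic reticulum chaperones and the unfolded protein response fell as a group, with a median difference of -0.11 over 20 measured members. Of these members 15 lay lower on both treated arrays than on both control arrays and 0 lay higher, where chance gives 16.7% of genes in each direction and 18.1% of all genes lay lower this way and 21.2% higher. Beside HSPA5, the calcium-binding chaperone gene CALR differed by -0.47 ± 0.070 (SE), and the protein disulfide isomerase genes PDIA3 and PDIA4 by -0.32 ± 0.081 and -0.20 ± 0.063 (SE). The list passed limma's camera with a preset correlation of 0.01 (adjusted p = 1.07e-07) and gave an adjusted p = 0.843 with an estimated correlation. No member passed over all clusters, and 2 were called lower when adjusted over the list alone. The 8 bacterial and phage control transcripts examined, which do not come from the cells, were also lower on treated arrays, by means of -0.19 to -0.62.

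The list of metallothionein genes, which encode metal-binding proteins, and a zinc exporter gene fell as a group with a median difference of -0.17 over 9 measured members (camera adjusted p = 0.00298, and adjusted p = 0.845 with an estimated correlation). MT1M differed by -0.32 ± 0.10 (SE) and MT1H by -0.30 ± 0.062 (SE), and 6 members lay lower on both treated arrays against 1 higher. With 1 array left out, MT1M differed by -0.43 to -0.20. Adjusted over the list alone, 1 member was called lower and over all clusters 0. Without Control replicate 2 the list's adjusted p was 0.0511, and the control transcripts' differences of -0.19 to -0.62 stand beside this list too.

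Lists of cell division and DNA repair also fell, beside the control transcripts' differences of -0.19 to -0.62. Replication-dependent histone genes had a median difference of -0.20 over 11 members (camera adjusted p = 6.46e-05, and adjusted p = 0.843 with an estimated correlation), with H2BC17 at -0.41 ± 0.061 (SE) and H2BC9 at -0.33 ± 0.073 (SE). Mitosis genes had a median of -0.076 over 29 members (adjusted p = 0.000199, and adjusted p = 0.845 with an estimated correlation), with CDK1, the mitotic kinase gene, at -0.28 ± 0.083 (SE), BIRC5, which encodes survivin, at -0.23 ± 0.068 and CCNB1, which encodes cyclin B1, at -0.19 ± 0.068. Genes of the G1/S transition and DNA replication had a median of -0.054 over 28 members (adjusted p = 0.00127, and adjusted p = 0.845 with an estimated correlation), with the replication licensing gene CDC6 at -0.26 ± 0.069 (SE) and FEN1, a flap endonuclease gene, at -0.16 ± 0.061. DNA repair genes had a median of -0.058 over 16 members (adjusted p = 0.0259, and adjusted p = 0.952 with an estimated correlation), and 8 of them had mean levels at or below the background features' median of 1.75. Of the histone genes 4 did so, and of the mitosis genes 5. CDK1 and H2BC9 lay just above that median over all arrays (1.82 and 1.81), and their treated means of 1.68 and 1.64 lay below it. In the order given, members lower on both treated arrays numbered 7 of 11, 17 of 29, 13 of 28 and 9 of 16, and those higher 0, 3, 2 and 0. No member of the 4 lists passed over all clusters, and adjusted over the list alone 2 histone genes were called lower and 0 genes of the other lists. Without Control replicate 1 the adjusted p of the mitosis list, which was 0.0537 among clusters at or above the upper quartile of mean expression, was 0.0805 and that of DNA repair 0.605, and DNA repair had 0.0877 without Cudraflavone C replicate 1, 0.348 after a further quantile normalization, 0.307 after cyclic loess and 0.147 among matched random lists, chosen after seeing the data.

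Sterol and lipid synthesis lists fell as well, again beside control transcripts lower by -0.19 to -0.62. Cholesterol synthesis genes had a median difference of -0.044 over 20 members (camera adjusted p = 0.00955, and adjusted p = 0.952 with an estimated correlation), with 9 members lower on both treated arrays and 0 higher. MSMO1, a sterol demethylation gene, differed by -0.28 ± 0.066 (SE), and SQLE, which encodes squalene epoxidase, by -0.21 ± 0.061 (SE). The mean level of MSMO1 was 1.83, close to the background features' median of 1.75, and its treated mean of 1.69 lay below that. Fatty acid synthesis genes had a median of -0.018 and a mean of -0.087 over 16 members (adjusted p = 0.0272, and adjusted p = 0.952 with an estimated correlation). The mean rested on 3 genes, called lower when adjusted over the list alone: ACLY, which encodes ATP citrate lyase, at -0.46 ± 0.064 (SE), the elongase gene ELOVL6 at -0.43 ± 0.083 and the stearoyl-CoA desaturase gene SCD at -0.38 ± 0.075. No member of either list passed over all clusters, and 0 cholesterol synthesis genes did when adjusted over the list alone. Without Control replicate 2 the adjusted p was 0.311 for cholesterol synthesis and 0.302 for fatty acid synthesis, and the latter was 0.0855 without Control replicate 1, 0.148 without Cudraflavone C replicate 1 and 0.0638 with an intensity trend in the variance. Cholesterol synthesis had 0.607 among clusters at or above the upper quartile of mean expression, and fatty acid synthesis 0.131 among matched random lists, chosen after seeing the data.

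Among the lists that rose, mesenchymal and matrix genes had a median difference of 0.090 over 24 members (camera adjusted p = 0.000342, and adjusted p = 0.952 with an estimated correlation). THBS1, which encodes the matrix protein thrombospondin 1, differed by 0.44 ± 0.065 (SE), the growth factor gene TGFB2 by 0.38 ± 0.064, and VIM, which encodes vimentin, by 0.23 ± 0.066. Of the 24 members 13 lay higher on both treated arrays and 1 lower, and 2 were called higher when adjusted over the list alone. Cell junction genes rose in the same comparison, with a median of 0.090 over 21 members (camera adjusted p = 0.0272, and adjusted p = 0.952 with an estimated correlation). JUP was followed by the desmosomal gene PKP2 at 0.29 ± 0.073 (SE), the beta-catenin gene CTNNB1 at 0.29 ± 0.081 and the tight junction gene TJP1 at 0.29 ± 0.087, and 12 members lay higher on both treated arrays against 4 lower. Adjusted over the list alone, 1 junction gene was called higher, and no member of either list passed over all clusters. The junction list had an adjusted p of 0.328 without Control replicate 2, 0.127 without Cudraflavone C replicate 2, 0.219 after quantile normalization and 0.217 after cyclic loess. The mesenchymal and matrix list had 0.105 among clusters at or above the upper quartile of mean expression. Among random lists matched on mean expression, chosen after seeing the data, the mesenchymal list had 0.0967 and the junction list 0.0986. The lower control transcripts (-0.19 to -0.62) leave a technical difference between the groups open for the lists that rose too, here and below.

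Immediate early genes and targets of ERK signalling rose with a median difference of 0.13 over 23 members (camera adjusted p = 0.00449, and adjusted p = 0.952 with an estimated correlation). EGR1 led the list, followed by KLF6 at 0.36 ± 0.077 (SE), FOSL1 at 0.31 ± 0.12, JUNB at 0.22 ± 0.081 and FOS at 0.21 ± 0.074, all transcription factor genes. Leaving out 1 array gave differences from 0.16 to 0.45 for FOSL1 and from 0.13 to 0.30 for JUNB. Members higher on both treated arrays numbered 12 and those lower 2, and 1 gene was called higher when adjusted over the list alone. Without Control replicate 1 the adjusted p was 0.227, and it was 0.0689 after quantile normalization, 0.0515 after cyclic loess and 0.126 among clusters at or above the upper quartile of mean expression.

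Targets of the aryl hydrocarbon receptor (AHR), a ligand-activated transcription factor, rose with a median of 0.14 over 8 members (camera adjusted p = 0.00279, and adjusted p = 0.952 with an estimated correlation). TIPARP, which encodes an ADP-ribosyltransferase of the PARP family induced by that receptor, differed by 0.43 ± 0.11 (SE), and the cytochrome P450 gene CYP1B1 by 0.24 ± 0.073 (SE). With 1 array left out, TIPARP differed by 0.28 to 0.58. Of the 8 members 7 lay higher on both treated arrays and 0 lower, and 0 passed when adjusted over the list alone or over all clusters. Targets of FOXO transcription factors also passed camera (adjusted p = 0.0456, and adjusted p = 0.952 with an estimated correlation), but their median over 21 members was 0.011 and their mean 0.12. The test rested on few members, 5 of which were called higher when adjusted over the list alone: BCL6, CITED2 at 0.48 ± 0.099 (SE), TXNIP at 0.40 ± 0.063, KLF6 and TRIB1 at 0.31 ± 0.068, and 0 passed over all clusters. Without Control replicate 1, Control replicate 2 or Cudraflavone C replicate 2 the FOXO list had an adjusted p of 0.227, 0.0985 and 0.0722, and it had 0.0678 among clusters at or above the median of mean expression. Among random lists matched on mean expression, a comparison of medians chosen after seeing the data, it lay near the middle, at percentile 44.5 (permutation adjusted p = 0.969).

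**Figure D2:**
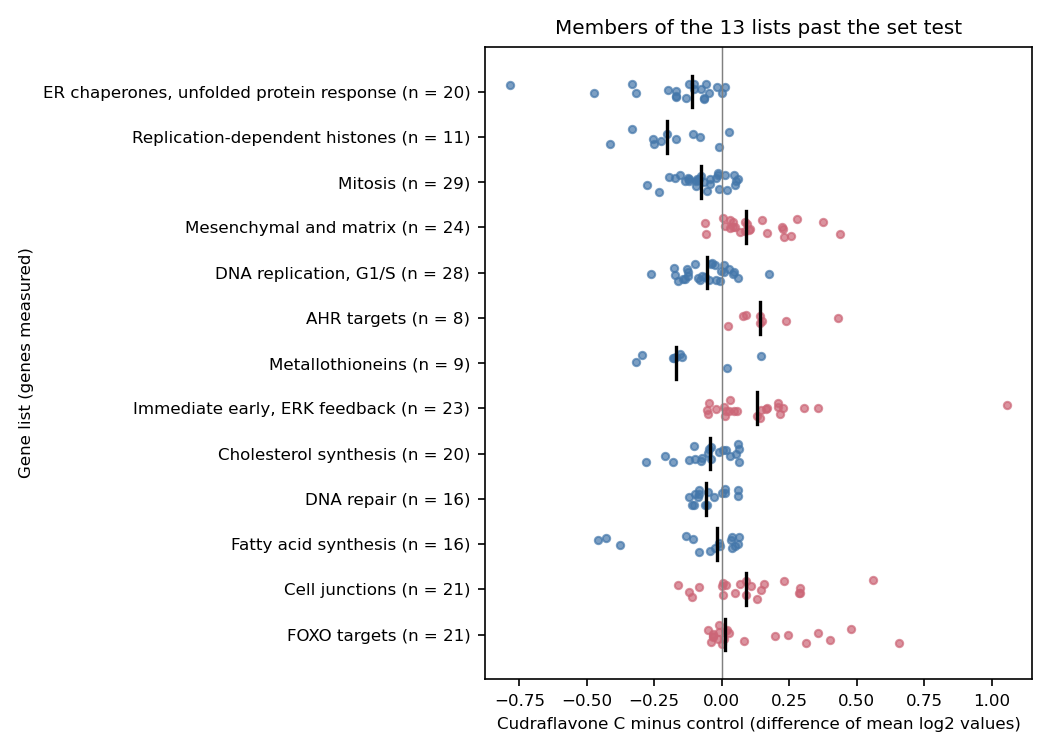
Differences between the mean log2 values of the cudraflavone C and Control arrays (horizontal axis) for each measured gene of the 13 lists that passed camera with a preset correlation (vertical axis, with the number of genes), as points, with black ticks at list medians. Blue lists had lower and red lists higher members by the test, with medians from -0.20 for histones to 0.14 for AHR targets, and most single genes differ by little.

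The other 30 of the 43 lists tested did not pass camera, with adjusted p from 0.209 to 0.976. Genes that promote apoptosis had a median of -0.027 over 21 members (adjusted p = 0.341) and those that inhibit it 0.021 over 8 (adjusted p = 0.676). PI3K-AKT pathway genes had a median of 0.047 over 19 members (adjusted p = 0.613), where RICTOR, a subunit gene of the mTORC2 kinase complex, differed by 0.20 ± 0.073 (SE). No member of these 3 lists passed over all clusters or adjusted over the list alone. Targets of p53 had an adjusted p of 0.209, with SFN, a 14-3-3 gene, at 0.57 ± 0.11 (SE), and ATF4 targets 0.444, with ATF3 at 0.41 ± 0.079 (SE) and SHMT2 at -0.26 ± 0.061. NRF2 targets had 0.976, although GPX2 belongs to them, and heat shock genes 0.667, xenobiotic metabolism 0.777, interferon response 0.676 and NF-kB and inflammatory genes 0.341. Spliceosome genes had 0.341, and passed as higher without Control replicate 1 (0.00592) or without Cudraflavone C replicate 1 (0.015). The list of cyclins and inhibitors of cyclin-dependent kinases, which also holds the kinase gene CDK6, had 0.573. It passed as lower after quantile normalization (0.0474). CDK6 itself differed by 0.43 ± 0.071 (SE), while means were lower for 8 of the 11 members and higher for 3. Nuclear genes of oxidative phosphorylation had 0.613, and passed as lower without Control replicate 2 (0.0372).

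Of the remaining metabolic and translational lists, glycolysis and hypoxia genes had an adjusted p of 0.238, with the glucose transporter gene SLC2A1 at 0.40 ± 0.062 (SE), and iron and heme genes and ribosome biogenesis genes both 0.559. The lists of tRNA synthetases (0.613), mitochondrial dynamics and mitophagy (0.676), lipoprotein secretion (0.892), fatty acid oxidation (0.901), estrogen response (0.613), autophagy and lysosome (0.976) and ribosomal proteins (0.976) did not pass. WNT targets and stem cell genes had 0.872, with SOX9, a transcription factor gene of intestinal progenitors, at 0.50 ± 0.083 (SE). Among these lists and those of the preceding paragraph, adjusted over the list alone, 1 gene each was called higher in glycolysis, NF-kB, cyclin-dependent kinase and WNT lists, and no member of any list passed over all clusters. Median, mean and test differed in sign for 8 lists that did not pass: ATF4 targets, heat shock, mitochondrial dynamics, interferon response, apoptosis inhibitors, NRF2 targets, autophagy and ribosomal proteins.

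Markers of differentiated enterocytes, the cell type Caco2 cells can resemble, had a median of 0.028 over 29 members (adjusted p = 0.613), with the carbonic anhydrase gene CA2 at 0.27 ± 0.083 (SE) and the intestinal alkaline phosphatase gene ALPI at 0.28 ± 0.12. FABP1, a fatty acid binding protein gene, was lower at -0.14 ± 0.064. Members higher on both treated arrays numbered 5 and those lower 3, and 9 had mean levels at or below the background features' median. Markers of other cell types did not pass either: the adjusted p was 0.676 for goblet and other secretory cells, 0.976 for enteroendocrine and tuft cells, 0.814 for fibroblasts, 0.356 for immune cells and 0.434 for endothelial cells. Their medians were 0.057, 0.028, 0.041, 0.077 and 0.044. The Control arrays also differed from each other with brightness: among the 3865 clusters with means from 4 to 5 the median of Control replicate 2 minus Control replicate 1 was 0.16, and treated minus control 0.061, or -0.024 against Control replicate 2 alone. Camera called 4 lists higher and 5 lower without Control replicate 1, and 5 and 8 with all arrays.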

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

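The comparison with random lists matched on mean expression was chosen after seeing the data. The count of clusters past the adjusted threshold was 0 higher and 0 lower under each normalization, filter, variance model and weighting tried, without each array in turn, at an adjusted p under 0.1 and in limma's treat against 1.2-fold. At an unadjusted p under 0.001 it was 73 higher and 56 lower. Camera called 5 lists higher and 8 lower. Higher lists numbered 3 after a further quantile normalization, 3 after cyclic loess, 2 among clusters at or above the upper quartile of mean expression, and 2 by matched random lists, and lower lists 4 in the upper quartile. Leaving out 1 array gave 3 to 6 higher lists and 5 to 8 lower lists, with the fewest higher without Control replicate 2 or Cudraflavone C replicate 2 (3 each) and the fewest lower without Control replicate 1 (5). The spread of a lone sample is then assumed to equal that of the other group. Camera with an estimated correlation called 0 higher and 0 lower, with 2 lists at an unadjusted p under 0.05, and directional fry called 0 and 0, with 4 at an unadjusted p under 0.05. The lists called at the preset correlation had estimates from -0.00996 (histones) to 0.545 (immediate early genes), so calls were lost at low estimates too. Apart from these changes of test, the cause was not tested. The FOXO list lay near the middle of matched random lists, at percentile 44.5 (permutation adjusted p = 0.969), and lost its call. The same comparison, which uses medians, also ended the calls of the mesenchymal (0.0967), junction (0.0986), fatty acid synthesis (0.131) and DNA repair (0.147) lists. In the 16 other settings, estimated correlation and fry apart, the endoplasmic reticulum list (adjusted p up to 0.00215) and the G1/S list (up to 0.0448) passed in the same direction, as did histones (up to 0.00258) and AHR targets (up to 0.0305) in the 15 that measured enough members. Across settings 98 genes were followed: those named for their differences, and eligible members of the called, p53, apoptosis, PI3K-AKT, NRF2 and ATF4 lists. Their lowest adjusted p in limma, in any setting that kept the gene, was 0.0797. Genes named from other lists, such as SLC2A1, SOX9 and CDK6, were not followed. With the replicate number as a block, 0 clusters passed in either direction, and 5 lists were higher and 8 lower, with no list call changed. Deviations of same-numbered arrays correlated at -0.059 across clusters, but 8 of 8 bacterial and phage control transcripts differed the same way between replicates 1 and 2 in both groups, and whether the numbers mark a shared handling is left open. Levels close to background limit what dim clusters can show.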

Other observations

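The tests of the endoplasmic reticulum list, of snRNA genes and of other pairings of the arrays were chosen only after the result was seen. Those of the actin list were written before its result. Genes named in this part were chosen after their values were seen.

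Actin cytoskeleton genes beyond those named by rule passed camera as higher with cudraflavone C at a preset correlation (unadjusted p = 7.56e-10), and gave p = 0.119 with an estimated correlation. A list of 48 genes of the actin cytoskeleton or linked to its regulation, left without the leading genes already seen and sharing 2 genes with the fixed lists, had 42 measured members with a median difference of 0.15, and 28 lay higher on both treated arrays against 3 lower, where chance gives 16.7% in each direction and 21.2% of all genes lay higher this way and 18.1% lower. ACTN4, which encodes alpha-actinin 4, differed by 0.57 ± 0.083 (SE), ACTR3 of the actin-nucleating complex by 0.47 ± 0.11, ILK, which encodes integrin-linked kinase, by 0.42 ± 0.073, and the cytoplasmic actin genes ACTG1 and ACTB by 0.36 ± 0.11 and 0.26 ± 0.060. At an unadjusted p under 0.05, 15 members were higher and 0 lower.

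Genes annotated as small nuclear RNA (snRNA) had lower values, mostly through those of the spliceosome. Over 24 genes the median difference was -0.24, against -0.0465 for 240 small nucleolar RNA (snoRNA) genes and 0.0181 for 17151 protein-coding genes, and 12 lay lower on both treated arrays and 1 higher. The leading genes were RNU4ATAC at -0.81 ± 0.063 (SE), RNU5A-1 at -0.75 ± 0.11, RNU12 at -0.53 ± 0.081 and RNU11 at -0.56 ± 0.11, while RNU6ATAC differed by -0.065 ± 0.083 and RNVU1-1 by 0.32 ± 0.19. Split after the values were seen, the 14 spliceosomal genes had a median of -0.31, with 10 lower on both treated arrays and 0 higher. The other 10, SNAR genes and RN7SK, had a median of -0.005 and ran from -0.50 to 0.23, with 2 lower and 1 higher. Near-identical copies in this class, such as SNAR-C3 and SNAR-C4, share probes, so its members are not independent.

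For the actin genes, a candidate explanation is a joint response of genes linked to the actin-responsive transcription factor SRF. The preset correlation's p of 7.56e-10 fits this and the estimated correlation's p of 0.119 leaves it open. Without each array in turn the former lay between 6.33e-10 and 7.34e-06. A difference between arrays that depends on brightness alone would leave the list among matched random lists, and its median lay above them (1-sided permutation p = 1e-04, the smallest the draws can give). The activity of SRF is untested, since the list is a broad one of actin genes drawn up after related genes were seen. The SRF gene, a member, differed by 0.19 ± 0.080 (SE) with separated groups. The known SRF targets CNN1, ACTA2 and TAGLN differed by 0.027 ± 0.096, 0.089 ± 0.082 and 0.12 ± 0.10 (SE) without separated groups. The members ACTB, ACTG1 and MYL9 differed by 0.26 ± 0.060, 0.36 ± 0.11 and 0.19 ± 0.10 (SE) with separated groups. These are picked members, and SRF targets were not tested as a class. Members with separated groups went both ways, such as TPM1 at 0.31 ± 0.064 and ANKRD1 at -0.060 ± 0.063, with 28 higher and 3 lower over the list. The lower control transcripts (-0.19 to -0.62) leave a technical difference between the groups open here too.

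For the endoplasmic reticulum list, Control replicate 1, the array farthest from the others, was tested as a source of the fall, and without it the adjusted p was 0.000666 at the preset correlation, while with an estimated correlation the list gave 0.843 on all arrays. The list's median also lay below random lists matched on mean expression (1-sided permutation p = 1e-04, the smallest the draws can give). The draws took genes as independent and permuted no arrays, so this p does not measure the spread between samples. Both values weigh against Control replicate 1 or brightness as the whole cause only if the members vary nearly independently. The list's estimated correlation was 0.031, itself imprecise with 2 arrays per group, so that stays open. The 0.843 does not measure it. Histones also gave 0.843 in that test, with an estimated correlation of -0.00996, below the preset 0.01. Neither the p without Control replicate 1 nor the permutation p addresses a technical difference shared by correlated genes. A response of the cells to the compound stays open as a hypothesis. So does a technical difference between the groups, since 8 bacterial and phage control transcripts differed by -0.19 to -0.62.

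For the snRNA genes, the median without Control replicate 1 was -0.19 and lay below matched protein-coding lists, as it did with all arrays (1-sided permutation p = 1e-04 in both, the smallest the draws can give). A lower yield of short RNAs in the treated samples may account for part of the difference. The snoRNA genes with a mean of at least 3 differed from matched genes by -0.068 (95% bootstrap interval -0.126 to 0.081, 37 genes), which is 0.070 above the snRNA genes' halved difference of -0.138, with an interval of -0.061 to 0.227 that spans 0. Over all 240 snoRNA genes, with a median level of 1.67 near background, the gap was 0.111 (0.013 to 0.180), and both sets lay low among matched lists (percentile 0.08 for the brighter genes). Yield and a cellular change cannot be told apart for these genes, because the interval for the brighter snoRNA genes spans 0, and the lower control transcripts on treated arrays (-0.19 to -0.62) leave other technical differences open.

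The 4 arrays can be paired into groups of 2 in 3 ways, too few for a share under 0.05. The real pairing gave 13 lists, 1 pairing of the 3 gave as many (the real pairing itself), and the highest other gave 5.

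The 8 bacterial and phage control transcripts examined were lower on treated arrays, by a difference of -0.62 for bioB, -0.58 for bioC, -0.41 for bioD, -0.19 for cre, -0.44 for dap, -0.41 for thr, -0.35 for phe and -0.25 for lys. Both treated arrays lay below both control arrays in each except phe, and all 8 were lower in both pairs of same-numbered arrays. Replicates 1 and 2 differed in the same direction in both groups for all 8.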
